A study of Homo sapiens with 20 samples.

How the data were processed

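Gene expression was measured by RNA-seq in 18 libraries of the prostate cancer cell line DU145, in 6 groups of 3, and the binding of FLAG-tagged menin was measured by CUT&RUN with 1 anti-FLAG library and 1 IgG library. The groups were taken from the sample titles: a parental line and a docetaxel-resistant derivative, each with a non-targeting guide and with 2 menin knockouts named KO2 and KO3. Per the labels' protocols, knockouts were made with CRISPR/Cas9 and grown from single colonies. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

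For RNA-seq, the authors deposited variance-stabilised (VST) counts on a log2-like scale for 60660 genes, all 18 libraries in 1 table. The submitters' processing notes name STAR, Salmon and DESeq2, with no roles or versions given in the sources used here, and the build GRCh38. For CUT&RUN they name Trim Galore 0.6.6, FastQC 0.12.1, Bowtie2 2.4.4, Picard, SAMtools, SEACR 1.3, bedtools 2.31.0, deepTools and HOMER. Zero counts sit at the lowest value of the table, 4.81, and differences of low genes are compressed. Inverting the transformation gave normalised counts, used here for levels and not for tests. Steps of a single count were visible in low genes, with 2-count steps 1.97 to 2.02 times as large, and gave estimated totals of 16200000 to 19700000 counts per library. Because Salmon estimates can be scaled gene by gene, these totals are approximate.

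For CUT&RUN, peaks were called with MACS 3 on the anti-FLAG library (17038226 fragments) against IgG (14186576 fragments) at a q-value of 0.05, per the file headers. The pileup signal, the fold enrichment over local IgG and the −log10 p and q of each peak are the authors' deposited values. There was no replicate, so peaks are described without a test between samples.

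Rows for the Y copies of pseudoautosomal genes (44) were left out. Symbols matched 60419 gene identifiers. Genes were tested if their mean was at least 0.5 above the lowest value, which left 16587. A linear model over all 18 libraries was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05 with a difference of at least 0.5 on the VST scale. Standard errors (SE) are those of the model. On simulated data over 16587 genes, the resistant against parental comparison recovered 68% of genes changed by 0.75 and 96% of those changed by 1, with 11 false calls. Changes were planted only in genes well above the filter, so recovery among lower genes was not tried.

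A set of 33 gene lists was fixed before the data were examined, and 30 had at least 3 measured members. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. In knockout comparisons a list member counts as risen or fallen when called the same way in both arms, and its difference is the mean of the arms. Named genes followed a rule also fixed beforehand: MEN1 and ABCB1; the 10 largest rises and 10 largest falls among called genes with non-overlapping libraries, clone-based names left out; the 5 largest interactions each way; 3 genes called in opposite directions by the arms; up to 4 called members per list; and genes near peaks. Some genes that the rule takes are not reported here. A readthrough locus shares reads with its neighbours and is uncertain.

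Comparisons against shared controls were set beside 100 simulations of unchanged groups. Positions are those of RefSeq on GRCh38, matched by symbol, for 15054 tested genes (90.8%). That table holds no strand, so the planned distance to a transcription start became the distance to either end of a gene. Shares of peaks carry exact Clopper-Pearson 95% intervals, which cover counting error only. Genes near peaks were compared with Fisher's exact test, two-sided, which treats neighbouring genes as independent.

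Alternatives planned beforehand were no filter, a stricter filter, median centring, quantile normalisation, the replicate number as a block, only the compared groups, other minimum differences, leaving out each library, and other distances and thresholds for peaks. Also planned were KO2 or KO3 alone in place of their mean, and an estimated correlation and fry for lists. Added after seeing the data were the leave-one-out and scaling fits for lists and for most named genes, leaving out libraries of groups not compared, the 2 arms of a line fitted alone against each other, peak tests by direction and in the parental line, and library weights. Weights estimated by REML stopped before convergence and were not used. Gene-by-gene weights, chosen after that failure, replaced them.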

Results

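The data describe DU145, an androgen-independent human prostate cancer cell line, as a parental line and as a line resistant to the taxane docetaxel. Each line carried a non-targeting guide or a knockout of MEN1, which encodes menin, a scaffold protein of the KMT2A and KMT2B histone methyltransferase complexes. There were 6 groups of 3 RNA-seq libraries, with estimated totals of 16200000 to 19700000 counts per library. Replicates correlated at r of at least 0.993 across genes, apart from parental KO2 replicate 1, which correlated at 0.961 to 0.965 with the other replicates of its group. Values below are differences on the VST (log2) scale with the SE of the limma model and n = 3 per group.

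MEN1 (ENSG00000133895.17, chromosome 11, 64803516 to 64811294, GRCh38) was lower in every knockout group. Its normalised count was 1780.5 ± 49.8 (SD, n = 3) in parental non-targeting cells, 178.4 ± 28.5 in KO2 and 230.2 ± 22.6 in KO3. In resistant cells it was 1744 ± 133 with the non-targeting guide, 303 ± 28.0 in KO2 and 284 ± 26.7 in KO3. MEN1 mRNA thus stood at 10.0% and 12.9% of the non-targeting level in the parental arms, and at 17.4% and 16.3% in the resistant arms. The difference of MEN1 between the resistant and parental non-targeting groups did not pass the test (−0.03 ± 0.11 SE, limma adjusted p = 0.847).

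ABCB1 (ENSG00000085563.15, chromosome 7, 87503017 to 87713295), which encodes the drug efflux pump P-glycoprotein, was near the lowest value in parental cells and high in resistant cells. Its normalised count was 2748 ± 33.4 (SD, n = 3) in resistant non-targeting cells and 0.628 ± 0.0494 in parental ones, a VST difference of 6.43 ± 0.15 SE (limma adjusted p = 2.14e-14), which the VST compresses at so low a parental level. With menin knockout in resistant cells ABCB1 rose to 6838 ± 55.8 in KO2 and 6750 ± 292 in KO3, 2.49 and 2.46 times the non-targeting level (limma adjusted p = 4.26e-06 and 4.79e-06). In parental cells the knockout arms differed from the control by 0.23 ± 0.15 and 0.25 ± 0.15, which did not pass the test. On this scale the knockout effect on ABCB1 differed between the lines by 1.05 ± 0.19 (limma interaction, adjusted p = 0.000191). The VST compresses the parental side of that difference, where counts went from 0.628 to 4.37 ± 4.63 (SD, n = 3) in KO2 and 3.54 ± 3.74 in KO3. These counts are too few for a fold, so the interaction is given on the VST scale only.

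**Figure D1:**
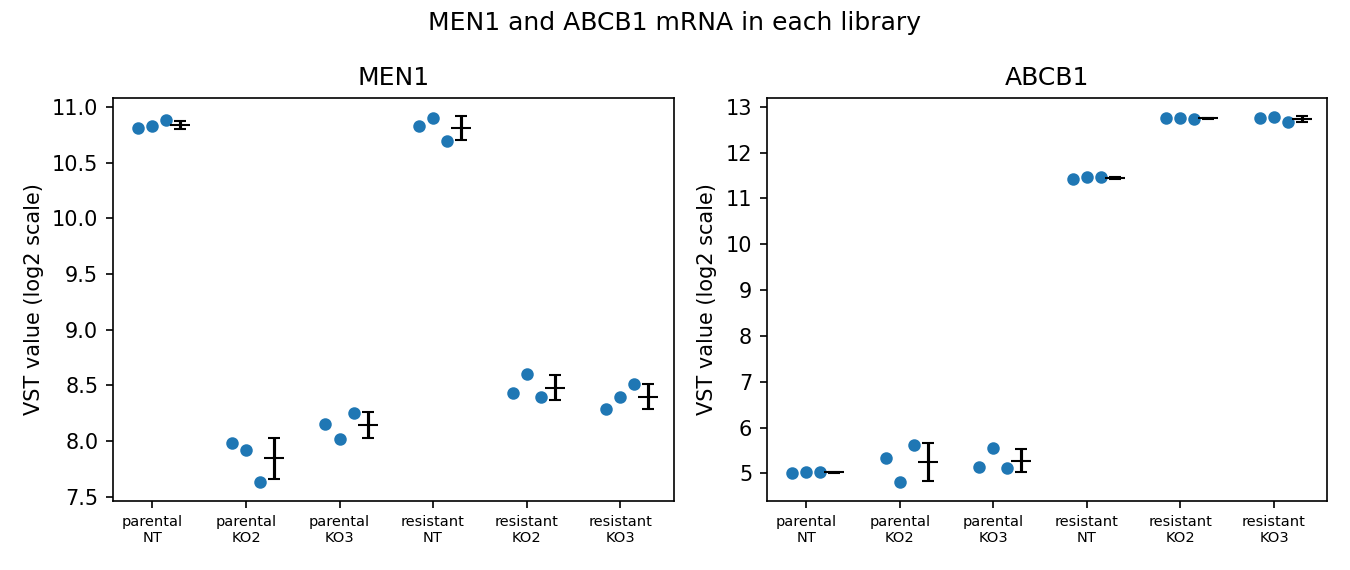
MEN1 (left) and ABCB1 (right) on the VST scale (log2) in each library, by group; points are libraries, and the bar beside them is the mean with its SD (n = 3). MEN1 is lower in all 4 knockout groups, and ABCB1 in resistant cells is higher with knockout (12.75 in KO2) than without (11.45).

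The comparison of resistant with parental cells, both with the non-targeting guide, asked what distinguishes the resistant line. Of 16587 genes, 1771 rose and 1788 fell. Beside ABCB1, the largest rises included COL5A2 (4.81 ± 0.19 SE) and COL3A1 (3.69 ± 0.10), which encode fibrillar collagens, CP (4.51 ± 0.13), the plasma copper carrier ceruloplasmin, and DPYD (3.96 ± 0.14), the enzyme that degrades pyrimidines. SEMA3E, MIR137HG, TNFRSF6B, MXRA8 and INA also rose, by 3.71, 3.41, 3.36, 3.26 and 3.11. BCHE, which encodes butyrylcholinesterase, fell from a normalised count of 1193.5 ± 146.2 (SD, n = 3) to 0 in all resistant non-targeting libraries. LCN2 (−3.25 ± 0.12), SCARA5 (−3.19 ± 0.12), CNTN1 (−2.82 ± 0.21), LRATD2, MISP, CLMP, THBD, TMEM200C and CYP24A1 (−2.35 ± 0.15) were the other large falls.

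Cholesterol synthesis had the largest median difference of the 30 lists. Of its 23 measured members, 19 rose and 0 fell, with a median of 0.96 (limma camera adjusted p = 2.67e-14), and the call held with an estimated correlation (adjusted p = 0.00114). STARD4 rose by 2.42 ± 0.22, HMGCS1 by 1.78 ± 0.21, and INSIG1 by 1.68 ± 0.13. Adjusted over the list alone, the count was also 19. HOXB, HOXC and HOXD genes had 9 rises and 2 falls of 19, led by HOXB6 (2.88 ± 0.10) and HOXB8 (1.93 ± 0.19), and mesenchymal genes had 5 rises, among them LOX (2.10 ± 0.13) and VIM (0.91 ± 0.09), and 1 fall of 19. Subunits of menin and COMPASS complexes had 4 rises of 19, KMT2A (0.96 ± 0.20), PSIP1, KMT2D and NCOA6. Lists that passed the test downward were G2/M and mitosis (9 fell and 1 rose of 30), NRF2 targets (8 fell and 1 rose of 22), oxidative phosphorylation (5 fell of 25) and MYC targets (5 fell of 25). With an estimated correlation these 7 calls were lost, with adjusted p = 0.224 for HOX genes, 0.0949 for mesenchymal genes, 0.205 for COMPASS subunits, 0.349 for G2/M, 0.0949 for NRF2 targets, 0.532 for oxidative phosphorylation and 0.224 for MYC targets. Counts adjusted over the list alone were the same in these 7 lists. Tubulin isotypes, a list that includes the beta-tubulins that taxanes bind, had 0 rises and 1 fall of 12. Genes neighbouring ABCB1 on 7q21 had 1 rise, ABCB1 itself, and 1 fall of 14.

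In parental cells, knockout against the non-targeting guide called 5953 genes in KO2 (2788 rose, 3165 fell) and 5686 in KO3 (2646 rose, 3040 fell). Both arms called 1803 genes up and 2178 down, 3981 in all, where independent lists would share 1025 and unchanged groups simulated against the same controls at most 1. Part of the excess may come from the shared controls, or from differences between colonies and controls other than the knockout, which the simulations leave out. Without rescaling falls were the majority, and rises made up 45.3% of the calls of both arms, but 53.1% with median centring and 51.7% with quantile normalisation, and the majority turned in each arm too. The arms differed from each other in 1858 genes, and 20 genes were called in opposite directions, led by PTGES (0.67 in KO2, −1.54 in KO3), NUPR1 and BIRC3. The KO2 group holds replicate 1, the library that stood apart. Without it the arms differed in 1101 genes, KO2 called 5692 and both arms called 4333. The number between the arms was also 3015 without KO2 replicate 2, 3401 without KO2 replicate 3, and 196 in a fit of the 2 arms alone, with 3185 at an unadjusted p under 0.05.

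The largest falls common to both parental arms were BCHE and LMO3, both at a count of 0 in all libraries of both arms, KLB (−5.60 and −5.01 ± 0.10 SE), a fibroblast growth factor co-receptor, CYP24A1 (−4.70 and −5.46), which inactivates vitamin D, and SPINT2, GSTM1, EREG, CLMP, EDIL3 and BRDT. INA (3.61 and 4.64 ± 0.13), a neuronal intermediate filament, NPTX1 (3.06 and 4.15), MAP3K14 (2.82 and 2.85), the NF-kB inducing kinase, CITED4, CD163L1, MYPN, SGK1, SERTAD4 and FOXRED2 rose most. RPL36A-HNRNPH2, a readthrough locus, also rose and is uncertain.

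Epithelial identity genes fell in parental knockout cells. Of 19 members 14 fell and 1, KRT18, rose, with a median of −2.20 (camera adjusted p = 3.43e-11, and adjusted p = 0.000398 with an estimated correlation). SPINT1 fell by 3.57 ± 0.11, EPCAM by 3.31 ± 0.09 and KRT19 by 3.25 ± 0.10. DNA replication and E2F targets rose, 16 of 30 with 0 falls (RRM2 1.68 ± 0.09, MCM3 1.32 ± 0.07; adjusted p = 0.00576 with an estimated correlation). ABC transporters fell, 5 of 10 with 0 rises (ABCC2 −3.43 ± 0.14, ABCC3 −2.16 ± 0.08; adjusted p = 0.0299 with an estimated correlation). A further 7 lists passed at the preset correlation and not at the estimated one. These were G2/M and mitosis (11 rose and 1 fell of 30, AURKA 1.38 ± 0.08; adjusted p = 0.138 with an estimated correlation), tubulin isotypes (6 rose of 12; 0.481), antigen presentation (5 rose and 1 fell of 17; 0.494), NF-kB and inflammatory genes (9 fell and 2 rose of 20; 0.0861), basal and squamous keratins and their partners (5 fell of 9, none of them a keratin, among them the laminin chain LAMB3, the integrins ITGA6 and ITGB4, and SFN; 0.0534), menin and COMPASS subunits (5 rose of 19 and MEN1 fell; 0.138) and DNA repair (6 rose and 1 fell of 24; 0.0889). Adjusted over the list alone, all 10 counts were the same.

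In resistant cells, knockout called 3821 genes in KO2 (1945 rose, 1876 fell) and 4073 in KO3 (2042 rose, 2031 fell). Both arms called 1719 up and 1603 down, 3322 in all, where independent lists would share 469 and simulated unchanged groups 0. The simulations hold only the spread between libraries, so a colony that differed from the control for another reason would also exceed them. If both labels held 1 culture, which is left open below, the arms would agree in any case. Between the arms limma called 0 genes, with 510 at an unadjusted p under 0.05 where chance gives 829. The median spread between libraries of different arms was 3.10 times counting noise, beside medians of 2.94 within KO2 and 2.67 within KO3. A fit of the 2 arms alone called 1 gene, with 1232 at an unadjusted p under 0.05.

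EPGN (5.83 and 5.84 ± 0.12 SE), an EGF-family ligand, IGFBP3 (5.05 and 5.32 ± 0.09), which binds insulin-like growth factors, TXNIP (3.89 and 3.97 ± 0.12), the thioredoxin inhibitor, ABCA1 (3.78 in both arms), the cholesterol exporter, and the neurofilament genes NEFL and NEFM rose most, with RTN1, TMEM265, PTGFRN and GPX3. COL5A2 (−6.50 and −6.29 ± 0.19), COL3A1 (−5.01 and −5.09 ± 0.10), LMO3 (a normalised count of 563.6 ± 30.7 (SD, n = 3) with the non-targeting guide, 0 in all KO2 libraries and 0.5 ± 0.9 in KO3), COBL, MIR137HG, KLB (379.9 ± 14.2, 0 in all KO2 libraries and 0.4 ± 0.6 in KO3), INA, BMP7, NDRG1 and WSCD1 fell most.

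Cholesterol synthesis genes fell in resistant knockout cells, 15 of 23 with 1 rise and a median of −0.78 (camera adjusted p = 1.96e-07, and adjusted p = 0.00981 with an estimated correlation). SQLE fell by 1.84 ± 0.09, HMGCS1 by 1.68 ± 0.18 and INSIG1 by 1.33 ± 0.11. ABC transporters rose, 6 of 10 with 0 falls, among them ABCG2 (1.74 ± 0.14) and ABCB1 (adjusted p = 0.0117 with an estimated correlation). NRF2 targets rose, 12 of 22 with 2 falls (GCLC 2.01 ± 0.14, AKR1C2 1.93 ± 0.11; 0.0117), and so did NF-kB and inflammatory genes, 7 of 20 with 0 falls (ICAM1 2.13 ± 0.07, CXCL1 1.45 ± 0.08; 0.00981). Antigen presentation had 12 rises of 17 (PSMB8 2.16 ± 0.11) and G2/M and mitosis 3 falls of 30, and both calls were lost with an estimated correlation (adjusted p = 0.316 for each). Adjusted over the list alone, G2/M had 4 falls and the other counts were the same.

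**Figure D2:**
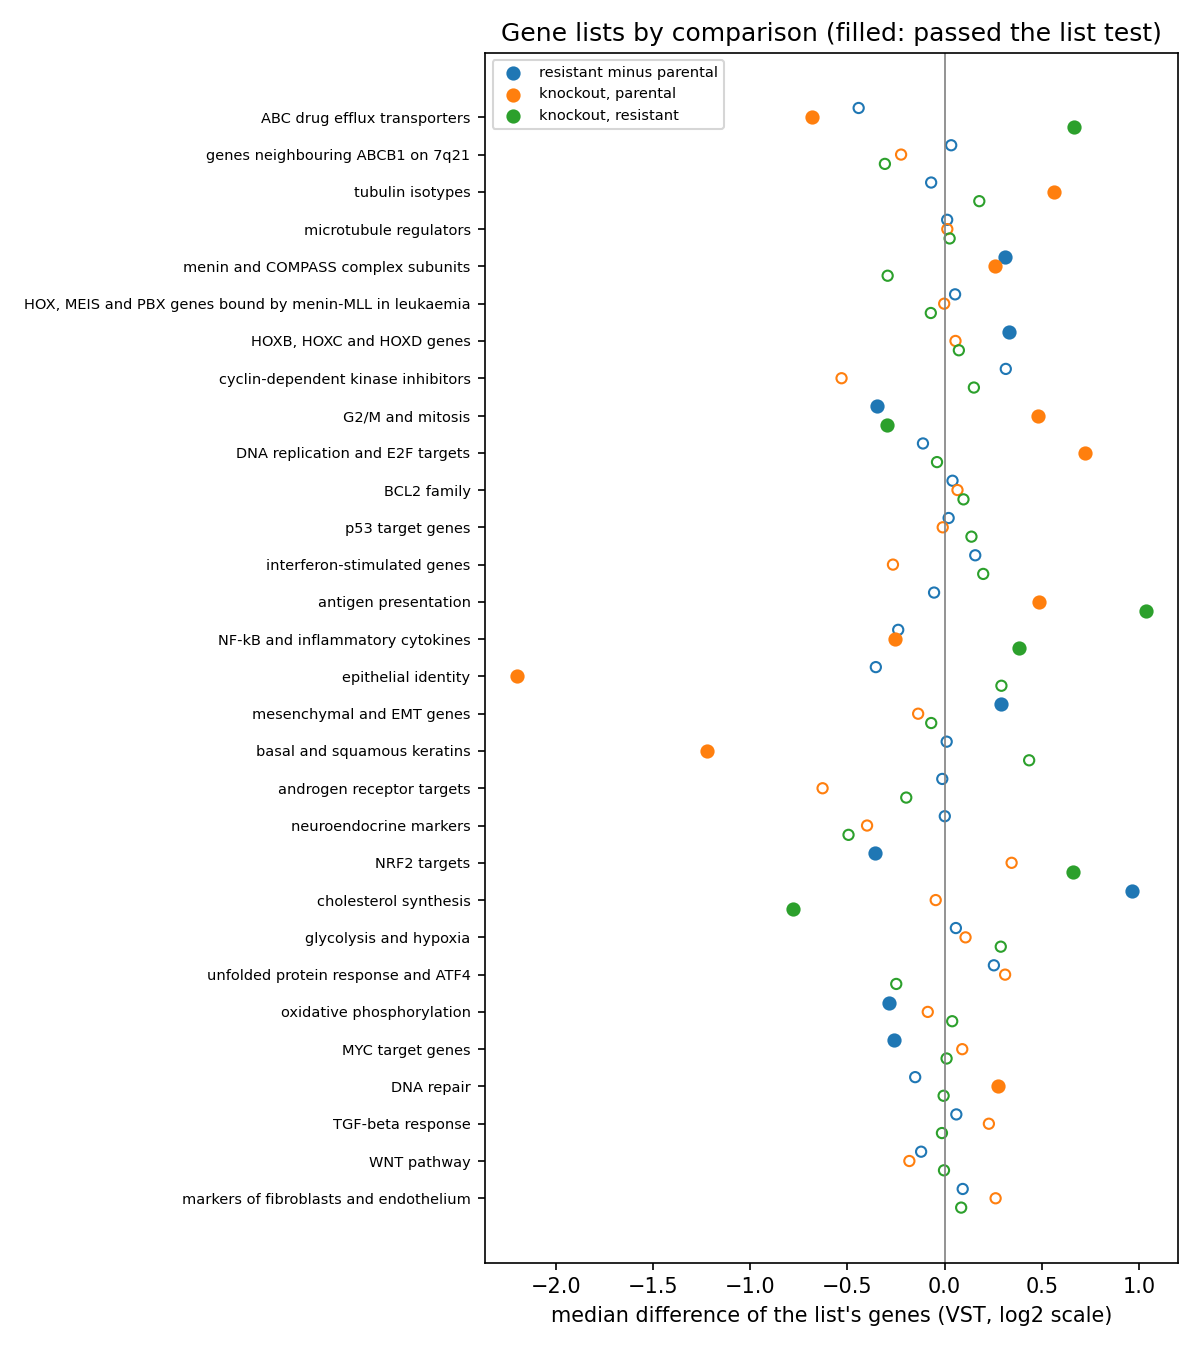
Median difference of each gene list (x axis, VST, log2 scale) for resistant minus parental and for the mean knockout effect in each line; filled points passed the camera test. Epithelial identity lies at −2.20 in parental knockout, and cholesterol synthesis at 0.96 in resistant cells and −0.78 on their knockout.

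Whether menin loss acted alike in both lines was tested with the interaction of knockout and line, which called 6905 genes (3620 higher and 3285 lower in the resistant effect, a majority that turned to 49.4% higher with median centring and 48.2% with quantile normalisation). Across genes, the mean knockout effects of the lines had a Pearson r of −0.00742 and a Spearman rho of 0.0164; genes are not independent replicates. Genes called in both arms of both lines moved the same way in 546 cases and opposite ways in 548, where independent lists would give 397 and 400. The largest interactions were CYP24A1 (7.31 ± 0.18 SE), ABCA1, TXNIP, EPGN and TMEM265 upward and COL5A2 (−8.09 ± 0.24), INA, MYPN, MIR137HG and COL3A1 downward. Among these the parental arms differed from each other for CYP24A1, EPGN, COL5A2, INA, MIR137HG and COL3A1. COL5A2 differed from the control by 0.06 ± 0.19 in KO2, which did not pass, and by 3.33 in KO3, COL3A1 by −0.92 ± 0.10 and 0.77, and EPGN by −0.69 ± 0.12 and 0.13, of which the second did not pass, while the resistant arms lay below both parental values for the collagens and above both for EPGN. LMO3, KLB and MEN1 fell in both lines.

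Of the 30 lists, 11 passed the test for the interaction, which is positive where the resistant effect was the higher. Epithelial identity (16 of 19 members higher, 2 lower; adjusted p = 0.000879 with an estimated correlation), ABC transporters (10 of 10 higher, ABCB1 on the VST scale only; 0.00352), NF-kB and inflammatory genes (13 of 20 higher; 0.00352), the basal and squamous keratin list (6 of 9 higher; 0.0298) and DNA replication and E2F targets (18 of 30 lower; 0.0102) held with an estimated correlation. The calls of G2/M and mitosis (23 of 30 lower, 1 higher; adjusted p = 0.0781 with an estimated correlation), cholesterol synthesis (13 of 23 lower, 2 higher; 0.0781), interferon-stimulated genes (10 of 21 higher, 1 lower; 0.0942), menin and COMPASS subunits (7 of 19 lower; 0.0932), DNA repair (10 of 24 lower, 2 higher; 0.101) and the unfolded protein response and ATF4 (9 of 20 lower, 4 higher; 0.577) were lost. Adjusted over the list alone, G2/M had 24 lower and the other counts were the same.

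**Figure D3:**
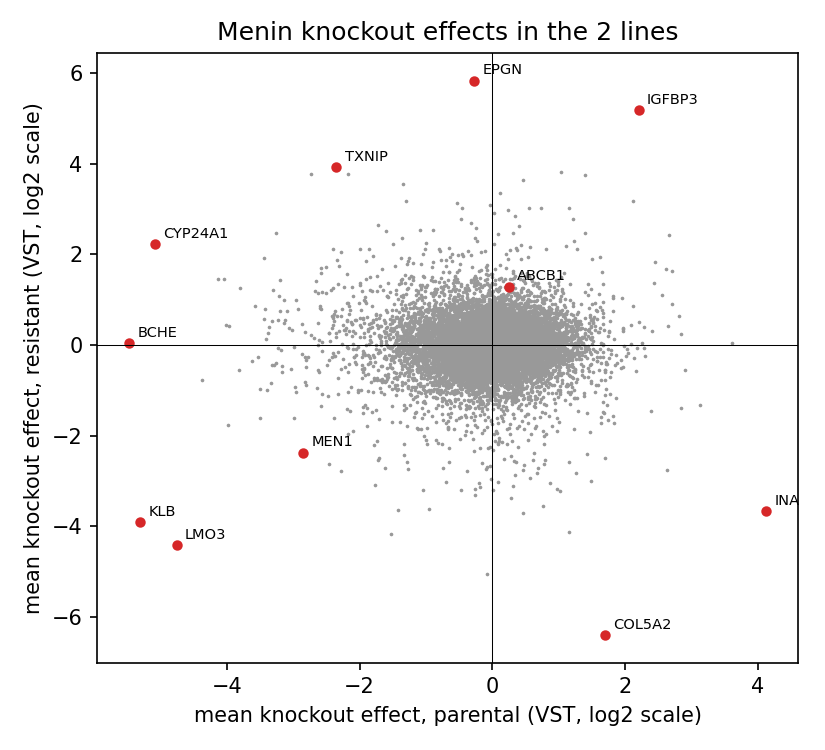
Mean knockout effect in parental cells (x axis) against resistant cells (y axis), both on the VST (log2) scale, 1 grey point per gene, with named genes in red. The effects did not correlate across genes (Pearson r −0.00742).

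Among the 3559 genes that distinguished resistant from parental cells, knockout in resistant cells moved 63.7% toward the parental value, and 61.1% moved that way in simulations with no knockout effect, because both comparisons use the resistant control libraries. The covariance of the differences was −0.0577, against −0.0120 simulated. Of genes also called in both resistant arms, 805 moved toward the parental value and 340 away, where independent lists would give 356 each. The covariance with the parental knockout effect was 0.109, against 0.0120 simulated, and 1173 genes were called the same way in both comparisons, with 229 opposite, where independent lists would give 427 each. Part of these excesses may come from the shared controls.

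CUT&RUN in resistant cells overexpressing FLAG-tagged menin gave 448 peaks with a median width of 283 bp and a median fold enrichment of 5.09, as the authors' peak caller gave them. Of these, 233 (52.0%, exact Clopper-Pearson 95% interval 47.3 to 56.7) had their summit within 1 kb of either end of a gene, where random positions gave a mean of 20.4. Of the 5 most significant peaks, 4 lay on chromosome 16 between 46387812 and 46398853, with fold enrichments of 1.27 to 1.59 and pileups of 1101 to 1806, and the nearest annotated gene end was that of SHCBP1, 179823 bp or more away. The other (chromosome 14, 31026542 to 31026979, fold 8.59) had its summit 439 bp outside the nearest gene end, that of STRN3, and inside AP4S1 (31025106 to 31096450). SHCBP1 and STRN3 did not pass the test on knockout in resistant cells (0.07 and 0.12 for SHCBP1, 0.07 and 0.08 for STRN3). AP4S1, an adaptor complex subunit named after its values were seen, rose in both arms (0.88 and 1.01 ± 0.14 SE, limma adjusted p = 8.62e-05 and 1.97e-05), and it overlaps STRN3, so its count is uncertain.

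Genes with a peak within 5 kb were called in both resistant arms in 84 of 391 cases (21.5%) against 3108 of 14663 other genes (21.2%), an odds ratio of 1.02 that did not pass the test (95% interval 0.787 to 1.303, Fisher's exact test, two-sided, p = 0.900). Within 1 kb the share was lower, 42 of 273 (odds ratio 0.671, Fisher's exact test, two-sided, p = 0.0167, adjusted p = 0.0334 over 14 tests). The called genes near peaks with the largest differences were KLB, PLAG1 (−2.76 and −2.78 ± 0.18 SE), ZHX1, RBM24, CHCHD7, PALS1, NEK7 and CGN, which fell, and RGMB (1.65 and 1.75 ± 0.10) and APOLD1, which rose.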

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

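The tests of a mislabelled library, of the resistant arms, of the KO3 arms alone and of arm precision, and counts of other splits of the samples, apart from those between arms, were chosen after results had been seen.

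The knockout effect differed between the lines in 6905 genes by the interaction test. Among lists, the resistant effect was higher for epithelial identity (median of the interaction 2.15), the basal and squamous keratin list (1.52), ABC transporters (1.48), NF-kB and inflammatory genes (0.85) and interferon-stimulated genes (0.54). It was lower for DNA replication and E2F targets (−0.78), G2/M and mitosis (−0.75), cholesterol synthesis (−0.57), unfolded protein response and ATF4 genes (−0.48), menin and COMPASS subunits (−0.45) and DNA repair (−0.36). With an estimated correlation, 5 of these 11 calls held. Among genes, the interaction was 7.31 for CYP24A1, 6.51 for ABCA1, 6.28 for TXNIP, 6.11 for EPGN, 5.95 for TMEM265 and 1.05 for ABCB1, whose parental counts (means of 0.628 to 4.37) are too few for a fold, so that value holds on the VST scale only. It was −8.09 for COL5A2, −7.78 for INA, −5.39 for MYPN, −5.28 for MIR137HG and −4.97 for COL3A1.

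Parental KO2 replicate 1 stood apart from the other replicates of its group. Its deviations followed gene span, introns included (Spearman rho −0.442). After that trend was removed their SD was still 1.675 times that of the next library, and 2.68 times the highest among libraries of other groups. The trend on gene span is thus not the whole cause, and transcript length was not tested. Cells of the non-targeting or resistant groups would bring their transcripts, and the highest median share was 0.01937%; only 5 genes could test parental KO3 as a source. It correlated better with its own replicates (0.9643) than with any other group (0.9534 at most), which speaks against a library of another group. A preparation that differed in another way, or a colony that differed, stays open and was not tested.

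The resistant KO2 and KO3 arms differed in 0 called genes. The median spread of pairs between the arms, 3.101 times counting noise, lay above the median of pairs within them, 2.807, with overlapping ranges (2.26 to 3.57 and 2.43 to 3.21), which leaves open whether 1 culture was sequenced under both labels. Leaving out parental KO2 replicate 1, whose noise enters the shared spread, also gave 0 called genes. Genes at an unadjusted p under 0.05 went from 510 to 1180 without it. Its noise thus lowered that number but does not alone account for the 0 calls. The 2 resistant arms alone gave 1 called gene, with 1232 at an unadjusted p under 0.05 where chance gives 829, and the same fit gave 196 in parental cells. The real division gave the largest excess of spread between arms over within (0.295) among 10 splits, too few for a share under 0.05, so colonies that respond alike and a single culture both remain open.

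Knockout effects of the lines did not correlate. Regional shifts of neighbouring genes were not the reason, as r was −0.001823 after removing the median of each 20 Mb window. Nor was parental KO2 replicate 1, as r was −0.06115 from the KO3 arms alone. The spread between libraries was not the reason either, as the parental arms correlated at 0.8524 with each other against at most 0.5303 in simulations. Those simulations hold only that spread, and both arms share their controls, so a departure of the control cells is not covered. What the lines' colonies carried besides the menin knockout was not tested, so a line-dependent role of menin and differences between single colonies both remain open.

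Other splits of the samples bear on these counts. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. There the real split gave 3559 genes for resistant against parental and the highest other 0 (1 of 10 as large), 5953 and 75 for parental KO2 (1), 5686 and 0 for parental KO3 (1), 3821 and 0 for resistant KO2 (1), 4073 and 0 for resistant KO3 (1), 1858 and 1 between the parental arms (1), 0 and 1 between the resistant arms (10), and for lists in resistant against parental 8 and 9 (2). Of 100 drawn splits, 1 gave as many genes as the 3322 of both resistant arms (highest other 1) and 1 as many as the interaction (highest other 4531). In both cases the 1 was the real division. A chance division of these libraries is thus an unlikely source of either count. The splits redrew guide labels within each line and never made the lines respond alike. For the interaction they therefore cannot tell whether the knockout effect differed between the lines. Every other draw for the resistant arms mixed controls with knockouts, so that test bears on the controls and not on the division into arms. The splits cannot exclude chance differences between colonies, since the libraries of a group may be technical copies. For both parental arms 2 of 100 gave 3981 or more. The other was a split that kept the controls whole and exchanged libraries between the arms (4333), and with controls mixed the highest was 712, so that test bears on the controls and not on the division into arms. For lists, 4 of 100 gave the 10 of parental knockout (highest other 11) and 2 the 11 of the interaction (11), while 36 of 100 gave the 6 of resistant knockout (9), so chance is not excluded for that number of lists.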

How the results depend on the processing

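The leave-one-out and scaling fits for lists and most named genes, those near peaks included, library weights, and all alternatives for the arms, were added after seeing the data. Counts of calls, other than those between arms, stayed within 1.5 times under filters, scaling, the compared groups alone, weights and each library left out. Ranges without 1 library were 3298 to 3700 for resistant against parental, 5692 to 6475 and 5533 to 5800 for parental KO2 and KO3, 3611 to 3951 and 3795 to 4198 for resistant KO2 and KO3, 3811 to 4333 and 3122 to 3426 for both arms in parental and resistant cells, 6682 to 7300 for the interaction, −0.0270 to 0.00302 for the correlation between lines, 62.3% to 64.8% for the share moved toward parental, and for lists 8 to 10, 9 to 10, 6 to 6 and 9 to 11. Without parental KO2 replicate 1, 5692 genes were called in parental KO2 and 4333 in both parental arms. Rises were 49.8% of the calls for resistant against parental and 50.1% for resistant KO3, so near balance that the majority turned under several alternatives. Between the parental arms the count depended on the libraries: 196 with the arms alone, 1180 with weights, 1101 to 3401 without 1 library (lowest without parental KO2 replicate 1, highest without replicate 3), 3404 with no minimum difference and 218 with a minimum of 1. Between the resistant arms it was 0 to 1 without 1 library, and 1 with no filter, with the replicate block and with the arms alone; the cause was not tested.

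The minimum difference sets the counts by construction. With none, 6038 genes were called for resistant against parental, 8547 for parental KO3, 6317 and 6727 for resistant KO2 and KO3, and 6260 and 5621 for both arms in parental and resistant cells. With a minimum of 1 the counts were 702, 1700 and 1696 (parental KO2, KO3), 959 and 1024 (resistant), 1101 and 858 (both arms) and 2700 (interaction). The share moved toward parental was 62.1% with none, 61.4% with 1 and 64.7% with quantile normalisation. The correlation between lines was 0.0425 for KO2 alone and −0.0612 for KO3 alone. Called lists fell to 1, 3 and 5 with an estimated correlation (resistant against parental, parental knockout, interaction), and fry, which asks another question, called 21, 24, 23 and 20.

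Replicate numbers did not meet the rule for pairing: same-numbered deviations correlated at a median of 0.0204, with 5 of 45 pairs over 0.1. As a hint from the data, 14 of 18 libraries were closest to their own number. Deviations from the mean of the other 2 replicates also correlated with gene span. Outside parental KO2, rho was −0.237 to −0.0406 in replicates numbered 1 and 0.0147 to 0.137 in those numbered 2. In those numbered 3 it was −0.100 to 0.118. Deviations within a group cancel out, so a negative rho in 1 replicate tends to raise rho in the others. Within parental KO2 it was −0.442 in replicate 1, and 0.373 and 0.423 in replicates 2 and 3, where the outlying replicate 1 enters the mean. The replicate block gave 3578 genes for resistant against parental and 6948 for the interaction. Apart from the count between the resistant arms, it moved no other count by over 1.5 times. Of 11742 values of named genes under alternatives, 75 lost their call, 8 gained it and 13 changed sign without being called. These were ITGAM in resistant knockout (0.00162 with centring, 0.0103 with quantile normalisation, and −0.0805 to 0.0292 without 1 library, with 0.00239 and 0.00445 between), STRN3 there (−0.00966 with quantile normalisation) and COL3A1 in parental knockout (−0.76 with the same, where the arms went opposite ways and the value is that of the smaller). The others changed sign only without 1 library, over ranges of −0.47 to 0.0254 (ITGAM) and −0.0798 to 0.0270 (MEN1) in resistant against parental, −0.00220 to 0.24 (COL1A1) in parental knockout, −0.0175 to 0.19 (SHCBP1) in resistant knockout, and −0.0219 to 0.15, with −0.0108 between (PRAME), in the interaction. Among peaks above the median significance, 113 were within 1 kb of a gene end. The odds ratio of peak genes fell below 1 within 1 kb (0.671), within 50 kb (0.956) and for either arm (0.999), while for either arm in parental cells it rose above 1 (1.04); the cause was not tested. Interaction fits use all libraries, so the compared groups alone add nothing there.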

Other observations

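The tests by direction near peaks, the parental test and the windows were chosen after results had been seen; so was the matched test in parental cells, while the predictions for the matched tests in resistant cells were set before their results were seen, that on position after the windows were known.

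Interferon-stimulated genes in resistant knockout had 8 rises and 1 fall of 21, led by OAS3 (2.78 ± 0.14 SE), without passing the list test (camera adjusted p = 0.0867). WNT pathway genes went both ways there, 2 of 17 up and 4 down (camera adjusted p = 0.697, not passed; adjusted over the list alone, 3 up and 4 down). WNT5A rose by 3.14 ± 0.09, and SFRP1, a secreted WNT antagonist, went from a normalised count of 205.8 ± 19.9 (SD, n = 3) to 0 in all libraries of both arms. TGF-beta response genes also went both ways, 6 of 20 up and 3 down with a median of −0.01, and did not pass (camera adjusted p = 0.674). THBS1 (3.01 ± 0.19) and INHBA (2.21 ± 0.11) rose, and TGFBR1, a receptor of the pathway, fell by 1.00 ± 0.19.

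In resistant cells, genes within 5 kb of an anti-FLAG peak were not called at a rate that differed past the test (odds ratio 1.02), while both tests by direction passed. There 67 of 391 fell (odds ratio 1.85, Fisher's exact test, two-sided, adjusted p = 9.42e-05 over 14 tests) and 17 rose (odds ratio 0.362, adjusted p = 4.99e-05). Genes near peaks were more highly expressed (median 9.55 against 8.75), yet 0 of 10000 sets matched on level and gene span held as many fallen genes, their median being 40. Some of these genes lie where neighbours fell together, as on chromosome 8 from 80000001 to 100000000 (medians −0.48 and −0.50 in the resistant arms). Sets matched on 20 Mb window and on level, the latter only as above or below the median of tested genes, had a median of 46 fallen genes. Of 10000 such sets, 0.03% held as many as 67, and gene span was not matched there. Level with span, and 20 Mb window, are thus each not the whole source. Finer level, span and window were not matched together. A single peak can lie within 5 kb of adjacent genes, and adjacent pairs such as PLAG1 and CHCHD7 are among those that fell. Both the Fisher tests and the matched sets take genes singly, so they may overstate the evidence. What menin does at genes near peaks was not tested, and the peaks come from 1 library without a replicate in cells overexpressing menin. In parental cells genes near peaks were called less often, 73 of 391 (odds ratio 0.688, adjusted p = 0.0102), though not among genes called in either arm (190 of 391, odds ratio 1.04, adjusted p = 0.969). Of those called in both arms, 20 rose (odds ratio 0.409, adjusted p = 9.42e-05; matched median 46). There 53 fell (odds ratio 1.02, adjusted p = 0.969; matched median 46, and 15.92% of sets held as many), and the difference between the lines was not tested.

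Neighbouring genes moved together. In parental knockout 9 windows of 20 Mb had a median of at least 0.3 in both arms the same way, and in resistant knockout 12, where 100 shuffles of gene positions gave at most 1. On chromosome 20, from 40000001 to 60000000, the medians were 0.55 and 0.54 in the parental arms and −0.12 and −0.13 in the resistant arms. On chromosome 18 over the same interval they were −0.65 and −0.68 in the resistant arms and 0.11 and 0.23 in the parental arms. As both arms moved the same way in these windows, the shifts lay between both arms and the control. Regional differences between the knockout colonies and the control cells, such as gene copy number, may be the source. Whether the control or an origin shared by the arms differed was not tested, and copy number itself was not measured. After the window medians were removed, 79.3% of the 3724 parental and 74.7% of the 3165 resistant genes called in both arms within windows still passed the minimum difference.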
